A study of Mus musculus with 449 samples.

How the data were processed

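RNA from mouse V6.5 embryonic stem cells infected with shRNA lentiviruses was hybridised, one sample per array, to one-colour Agilent prototype arrays designed on the mm9 build. The authors processed the scans with Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), and the deposited values are spot signals as intensity, with local background also as intensity. Per the file headers the processed signal is corrected for background and spatial trend within each array, and it is neither scaled between arrays nor on a log scale. The fields used per spot were the processed signal, the median signal, the median local background, the flag for a signal well above background and the flags for outlying spots. Of the samples labelled, 405 had a file in the sources used here and the 44 of one further batch were not used here.

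Each array held 62976 spots, of which 1319 were control spots and were left out, leaving 59452 probes. Of these, 26910 were named by a RefSeq accession, 18214 by a genomic region alone and 14328 otherwise. Accessions were paired with symbols by the RefSeq table of assembly GRCm38.p6, used for names alone, which gave 18346 named genes, 17974 of them protein coding. Regions are given on mm9, per the file headers, and 5 arrays lacked the build in their header. A gene with several probes was represented by its brightest probe, chosen by the mean over all arrays, which applied to 9099 features. Values of spots carrying an outlier flag were left out, and the 5336 of 24078060 probe values left without any were filled with the mean of the probe in the array's group, or in the controls of the batch where the group had none. Values were log2 transformed and the 75th percentile of each array was subtracted. Features well above background on at least 2 arrays of 1 group were tested, which left 29961 features: 15689 named genes, 6850 regions and 7422 others.

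Class, target, hairpin and batch were read from the labels, and the slide and scan day from the file headers. For protein genes the labels gave only an accession, with or without a suffix, and this was taken as the hairpin. All tests on single genes used limma 3.58.1 under R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. For the class comparisons the arrays of one hairpin in one batch were averaged, so that a hairpin was one replicate, and the batch was a term of the model. For single knockdowns 1 model held all 405 arrays with a mean per hairpin and batch, and each knockdown was set against the control arrays of its own batch. In this model knockdowns with 1 array are assumed to vary like the others. Genes counted as changed per knockdown in the comparison of classes also had an absolute log2 fold change of at least 1. The labels do not say whether the arrays of one knockdown came from separate cultures, so p-values measure only the spread between the samples as given. Replicate numbers were not used to pair samples. Levels of Pou5f1 over the lincRNA knockdowns and levels of the targeted genes were adjusted over the knockdowns and targets tested. Where a gene was well above background on no array of one group, its change is given as a bound. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own.

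Gene lists were fixed before the data were examined, as were the comparisons, their tests and most alternatives. The lists (genes measured) were pluripotency (27 of 30), trophectoderm (20 of 20), primitive and visceral endoderm (18 of 20), mesoderm (20 of 20), neuroectoderm (18 of 20), primed epiblast (12 of 12), 2C-like (8 of 14), interferon response (18 of 20), p53 targets (20 of 20), integrated stress response (20 of 20), cell cycle (19 of 20), Polycomb and chromatin factors (20 of 20), and feeder fibroblast markers (29 of 30). Each was tested with camera on limma's statistics at an inter-gene correlation of 0.01, and again with the correlation estimated from the residuals, with adjustment over all knockdowns and lists. The lists share members, so their tests are correlated. Targeted genes were not left out of the lists, so the target of a protein gene hairpin enters any list that holds it. Among list calls in single knockdowns, the mean and the median of the list differed in sign for the cell cycle list of linc1505 in batch 2 and the endoderm list of linc1588, and neither call held with an estimated correlation.

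Genes are named in the text by a rule fixed before the data were examined. For each class comparison and each Pou5f1, XM_132755 and Sox2 knockdown it takes the 10 largest rises and the 10 largest falls among genes with adjusted p under 0.05. These had to be well above background on at least 50% of the arrays of one side and, for knockdowns, on the same side of the control mean in every knockdown array. Members of the fixed lists may be named as well, and those named in other knockdowns were picked after their values were seen. For lincRNA knockdowns the rule takes the 5 with the most changed genes among those with at least 2 arrays, each with its 3 largest rises and falls. For targeted genes it takes the 5 largest and the 5 smallest falls.

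One knockdown is labelled only with XM_132755. It was taken as that of Nanog when the tests were set, an identity that the sources used here do not establish, so its own target was not measured. The planned counts of lincRNA knockdowns with lower Nanog and of lincRNA knockdowns with a changed neighbouring gene were not run, since neither Nanog nor the loci of the targeted lincRNAs were paired with array features in the sources used here.

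Profile similarity was measured as Pearson's r across genes between log2 fold changes, with the control arrays split at random so that compared profiles did not share controls, and tested by permutation. Counts per knockdown were compared by a two-sided permutation test with 1e+05 resamples. Alternatives tried were normexp background correction (offset 50) on the median signals, quantile normalisation, no filter, a filter on at least 50% of all arrays, the mean of a gene's probes, other sets of control arrays, the mean of the feeder markers as a covariate, slide, scan day or replicate number as blocks, hairpin as a random block (with the correlation estimated on 1000 drawn genes), batch 1 alone, fits on fewer arrays, and leaving out arrays in turn. The number of arrays limits precision. It was tested on simulated data, drawn from normal distributions with each gene's mean and spread, into which changes of known size were planted (29961 features, 100 or 200 planted per size). Of planted changes of log2 size 1 and 2, limma recovered 57% and 92% for the Pou5f1 knockdown in batch 1, 45% and 86% in batch 2, 43% and 80% for the XM_132755 knockdown in batch 1, 42% and 80% in batch 2, and 54% and 81% for Sox2. Of planted changes of 0.25 and 0.5 it recovered 48% and 88% for lincRNA against control hairpins, 39% and 79% for protein gene against control hairpins, and 53.5% and 95.5% between the lincRNA and protein gene hairpins. False calls numbered 6 to 18 per comparison, and no planted change was called in the wrong direction. The draws were independent between genes and between arrays or hairpins. They held no slide effects and no control hairpins that differ in many genes at once, so these rates need not hold for the real arrays.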

Results

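Mouse V6.5 embryonic stem (ES) cells, a line kept on fibroblast feeders, were infected with lentiviruses that each carried one short hairpin RNA (shRNA). The hairpins were directed against long intergenic noncoding RNAs (lincRNAs), against protein-coding genes with regulatory roles as positive controls, or against sequences that are not mouse genes (GFP, LacZ, luciferase and RFP, with the pLKO vector) as controls. Feeders resistant to puromycin were added after infection, infected cells were selected, and RNA was taken on day 4 from pools of 3 wells. The arrays measured transcripts of named genes and of intergenic regions. They comprised 284 arrays with 151 lincRNA hairpins, 80 arrays with 42 protein gene hairpins and 41 arrays with 32 control hairpins, counting a hairpin once per batch. Batch 1 held 227, 76 and 30 of these arrays and batch 2 held 57, 4 and 11. Most single knockdowns had 2 arrays.

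The share of spots well above background was similar across classes and higher in batch 2. Its median over control arrays was 56.7% in batch 1 (range 43.2% to 69.3%) and 60.7% in batch 2 (57.9% to 64.4%). Over lincRNA arrays it was 54.7% in batch 1 (44.2% to 66.7%), and over protein gene arrays 55.2% (44.6% to 65.4%). Feeders were in the wells, so the samples could also hold feeder RNA. The feeder markers cannot tell it from expression of the same genes by the infected cells. The mean log2 level of the feeder markers in controls was 2.57 ± 0.33 (SD, n = 30) in batch 1 and 4.1 ± 0.19 (SD, n = 11) in batch 2. That of the pluripotency list was 4.59 in batch 1 and 3.90 in batch 2. The first principal component, with 24% of the variance, split the arrays mainly by batch (88.7% of it), so knockdowns were set only against controls of their own batch. The second component (14.3%) followed the slide, which took up 91.1% of it.

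The level of each targeted gene in its own knockdown shows whether the hairpin worked. Pou5f1, the core POU-domain factor of pluripotency, had the largest fall of the targets measured. In batch 2 it fell by 4.09 ± 0.22 on the log2 scale (SE, n = 2), which left 5.88% of the control level. In batch 1, on 3 arrays, 11.7% was left. The heterochromatin protein gene Cbx3 fell by 3.36 ± 0.14 (n = 2), leaving 9.75%, and the H3K9 methyltransferase gene Setdb1 fell by 3.29 ± 0.18 (n = 2), leaving 10.2%. Eed, which encodes the core scaffold of Polycomb repressive complex 2, fell by 2.97 ± 0.21 (n = 2), leaving 12.8%. The smallest falls that passed the test were those of Mycn (67.2% left), Sox2 (66.2%) and Ruvbl1 (61.9%). Klf2 differed by -0.04 ± 0.37 (n = 3, adjusted p = 0.905), and Trp53 by -0.69 on 1 array. In all, 38 of 41 knockdowns with a measured target had it lower, counting Pou5f1 once per batch. These were 38 of the 40 protein gene knockdowns measured, whose targets had a median log2 fold change of -1.81, or 28.6% left. Of the lower targets 5 were measured on 1 array, with a spread borrowed from the other knockdowns. Only 1 lincRNA target was matched by name to a feature, C330024D21Rik for linc1536. It was at background on both sides, so the depletion of the lincRNAs themselves was not measured here. Knockdown of a lincRNA therefore means only that a hairpin directed against it was used.

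**Figure D1:**
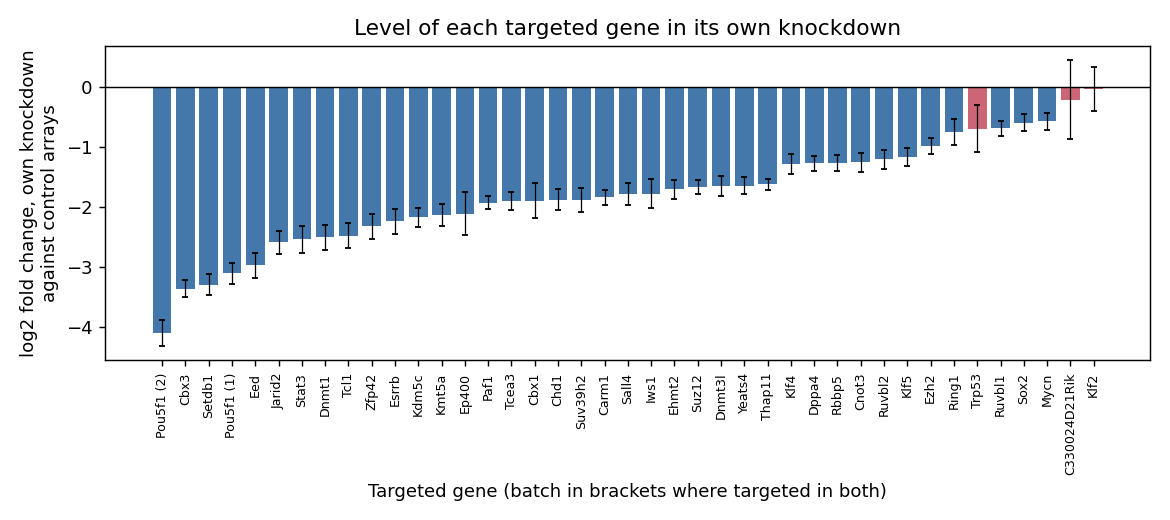
Log2 fold change of each targeted gene in its own knockdown against control arrays of the batch, with bars as standard errors and targets along the x axis. Pou5f1 in batch 2 (-4.09) and Cbx3 (-3.36) lie lowest, and Klf2 (-0.04) lies at the control level.

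Pou5f1 holds ES cells in the pluripotent state, and its loss turns them toward trophectoderm, so its knockdown tests what the array can see. In batch 1 the trophoblast gene Plac1 rose by 6.47 ± 0.38 on the log2 scale (SE, n = 3 against 30 control arrays, adjusted p = 5.2e-39). The trophoblast factor Hand1 rose by 6.44 ± 0.34, the placental homeobox genes Rhox6 and Rhox9 by 5.99 ± 0.27 and 5.70 ± 0.25, and the trophectoderm regulators Elf5 and Cdx2 by 5.46 ± 0.48 and 5.31 ± 0.43. In the 30 batch 1 controls Plac1, Hand1, Elf5 and the mesoderm gene Mixl1 were well above background on 16, 13, 1 and 17 arrays, which applies wherever their batch 1 changes are given. The epiblast growth factor gene Fgf5 (-4.80 ± 0.18), the Nodal antagonist gene Lefty1 (-4.53 ± 0.25) and the Nodal co-receptor gene Tdgf1 (-3.01 ± 0.24) fell. So did the kinase gene Pim2 (-3.64 ± 0.19), the mesoderm factor T (-3.73 ± 0.41) and the orphan receptor gene Nr0b1 (-2.10 ± 0.15).

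Across the array 9595 features changed in batch 1, 4527 upward and 5068 downward, and 3267 of them by at least 2-fold. Besides the genes above, the rule for naming genes took 3830417A13Rik (6.11 ± 0.31), Tnnt3 (5.17), Gm9 (4.83) and Dppa1 (at least 52.0-fold higher) among rises. Among falls it took Trim67 (-6.30 ± 0.19), Ltb (-4.88 ± 0.20), Mmp25 (-4.53), Myb (-4.37 ± 0.16), Nsg2 (-4.34) and Car14 (-4.27 ± 0.20). The endoderm gene Cer1 was at least 28.3-fold lower. Eomes, a trophoblast and mesoderm factor, differed by 0.50 ± 0.28 (adjusted p = 0.181). Intergenic regions changed too: 414 rose and 930 fell. Trim67, Mmp25, Myb and T were well above background on 2 of the 3 knockdown arrays and Nsg2 on 1. A region at 50408456 to 50410370 on chromosome X rose by 3.01, and one at 67552754 to 67560847 on chromosome 8 fell by 4.17.

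In batch 2, with 2 arrays against 11 controls, the epiblast and pluripotency genes fell again while the trophectoderm genes went different ways. Rhox6 rose by 4.82 ± 0.34 (SE, n = 2), Rhox9 by 4.55 ± 0.32, Hand1 by 2.81 ± 0.44 and Plac1 by 2.27 ± 0.48. Cdx2 fell by 1.54 ± 0.55 (adjusted p = 0.0161) and Eomes fell by 3.03 ± 0.36, and Elf5 was at background on both knockdown arrays. The naive-state factor Esrrb (-1.34 ± 0.16), Nr0b1 (-3.66 ± 0.19), Tdgf1 (-4.71 ± 0.30) and Fgf8 (-5.77 ± 0.36) fell, and T was at least 151-fold lower. The topoisomerase gene Top2a (-2.02 ± 0.16) and the replication factor Mcm3 (-1.96 ± 0.17) fell, and the p53 targets Cdkn1a and Mdm2 rose by 1.33 ± 0.25 and 1.30 ± 0.15. Asb9 (4.97 ± 0.71) and Trp63 (3.35 ± 0.38) were among the largest rises. Trh (-5.92 ± 0.26) and Wnt8a (-5.40 ± 0.36) were among the largest falls, with Nphs1 at least 61.3-fold and Trim67 at least 59.8-fold lower. Asb9 and Trp63 were well above background on 1 and 2 of the 11 controls, and Wnt8a and Otx2 on 1 of the 2 knockdown arrays. In all 11457 features changed, 5824 upward and 5633 downward. Of features changed in both batches 2865 were higher in both, against 880 by chance, 2778 were lower in both, against 953 by chance, and 475 had opposite signs. A test of the difference between batches called 6114 features, among them Cdx2 (batch 1 minus batch 2, 6.86 ± 0.69), Plac1 (4.20) and Hand1 (3.63), while Fgf5 did not pass (0.18, adjusted p = 0.717).

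The fixed gene lists put these changes side by side. The trophectoderm list rose in batch 1 by a mean of 3.35, with 16 of 20 genes higher (camera adjusted p = 2.0e-37, and 9.9e-13 with an estimated correlation). In batch 2 its mean was 1.11, with 11 genes higher and 2 lower (1.8e-04, lost with an estimated correlation, adjusted p = 0.145). The primed epiblast list fell in both batches, with means of -1.80 in batch 1 (9 of 12 lower) and -2.18 in batch 2 (10 lower, 1 higher), and both calls held with an estimated correlation (adjusted p = 0.011 and 0.00766). That of batch 1 was lost against clonetechGfp_437 and pLKO, the 2 most replicated control hairpins, alone (adjusted p = 0.0933). The pluripotency list fell in batch 2 (mean -1.72), with 22 of 27 genes lower (adjusted p = 1.0e-04 with an estimated correlation). In batch 1 it averaged -0.88, with 13 lower and 2 higher (2.0e-07, but adjusted p = 0.088 with an estimated correlation). The cell cycle list fell in batch 2 (mean -1.23), with 18 of 19 lower (4.5e-05 with an estimated correlation), and averaged -0.21 in batch 1 (adjusted p = 0.14).

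Other list calls of the Pou5f1 knockdowns were lost with an estimated correlation. The feeder markers averaged 0.86 in batch 1 and 1.14 in batch 2, with 26 of 29 higher in each (adjusted p = 0.219 and 0.23 with an estimated correlation). The mesoderm list averaged -0.87 (0.588) and -1.70 (0.266), and the interferon list 0.90 (0.444) and 1.11 (0.404). The neuroectoderm list averaged -0.64 in batch 1 (0.15). The p53 target list averaged 0.66 in batch 2 (0.114) and the Polycomb list -0.53 (0.145), neither called in batch 1 (adjusted p = 0.254 and 0.641). The integrated stress response list (adjusted p = 0.433 and 0.494), the endoderm list (0.0917 and 0.507) and the 2C-like list (0.471 and 0.287) were not called in either batch.

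**Figure D2:**
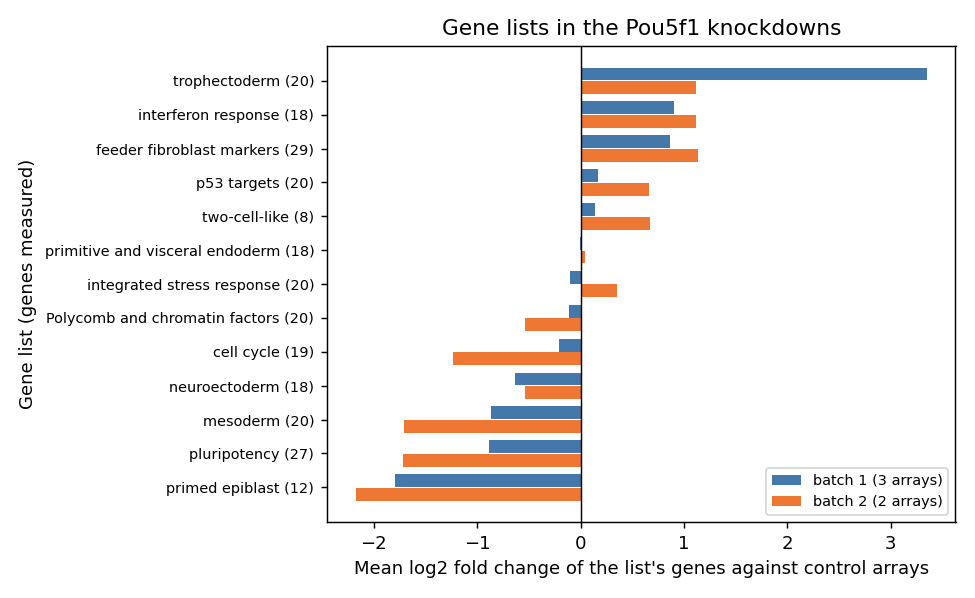
Mean log2 fold change of each gene list in the Pou5f1 knockdowns against control arrays of the batch, as bars for batch 1 (3 arrays) and batch 2 (2 arrays). The trophectoderm list averages 3.35 in batch 1 and 1.11 in batch 2, and the cell cycle list -0.21 and -1.23.

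The XM_132755 knockdown was chosen as a further pluripotency control, and with all controls of its batch its effect was far smaller. In batch 2 Khdc3, which encodes an oocyte and early embryo protein, fell by 2.13 ± 0.21 (SE, n = 2), and the neuronal endosome gene Nsg2 fell by 2.52 ± 0.21. Falls were smaller for Esrrb (-1.03 ± 0.16, adjusted p = 8.1e-07), Nr0b1 (-0.84 ± 0.19, adjusted p = 0.0041) and Zfp42, a marker of naive ES cells (-0.79 ± 0.16, adjusted p = 3.6e-04). The neural factors Zic2 (-1.31 ± 0.30) and Pax6 (-1.22 ± 0.23) fell too. D630039A03Rik was at least 14.4-fold lower, Krt23 at least 8.55-fold and Spon1 at least 3.51-fold. Rises included Sprr3 (2.24, well above background on 1 of 11 controls), Fabp7 (1.48 ± 0.42) and the p53 targets Eda2r (0.57 ± 0.15) and Trp53inp1 (0.44 ± 0.10). In batch 1 Khdc3 (-1.31 ± 0.20, n = 2), Spon1 (-1.54 ± 0.37), D630039A03Rik (-1.53 ± 0.22) and Tspan1 (-1.65 ± 0.22) fell. Eomes rose by 1.36 ± 0.34 (adjusted p = 0.0226) and Cyp2f2, Sall3 and Frzb by 1.61, 1.52 and 1.47, while Esrrb (-0.35, adjusted p = 0.404), Nr0b1 (-0.13, 0.917) and Zfp42 (-0.07, 0.957) did not pass the test.

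The XM_132755 knockdown changed 210 features in batch 1, 66 upward and 144 downward, and 399 in batch 2, 65 upward and 334 downward. The batch 1 count rests on both arrays: without replicate 1 it was 40 (5 upward, 35 downward), without replicate 2 it was 37 (22 upward, 15 downward), and with the scan day as a block 51, but against clonetechGfp_437 and pLKO alone it was 5255. Of the features called in both batches 53 were lower in both batches, against 1.61 by chance, 1 was higher in both and 0 had opposite signs; limma called 10 features as differing between batches. In batch 2 the pluripotency list averaged -0.38, with 5 genes lower over all genes and 13 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0066 with an estimated correlation). The p53 target list averaged 0.29, with 2 higher and 9 when adjusted over the list alone (0.0113). Neither list held in batch 1, where the pluripotency list averaged -0.02 (adjusted p = 0.61) and the p53 list 0.22 (7.8e-06, but 0.0939 with an estimated correlation). The neuroectoderm (-0.19), feeder (0.34), interferon (0.31) and cell cycle (-0.16) lists in batch 2 and the feeder (0.29), primed (0.37), interferon (-0.36) and endoderm (0.26) lists in batch 1 were called only at the preset correlation, with adjusted p from 0.105 to 0.497 at an estimated one. The mesoderm list in batch 1 averaged 0.67, with 0 genes called over all genes by limma and 8 higher and 1 lower when adjusted over the list alone (2.3e-05, but adjusted p = 0.232 with an estimated correlation). With the controls of its own scan day alone, limma called 0 features in batch 1 and 1999 at an unadjusted p under 0.05.

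Sox2 partners Pou5f1 at pluripotency enhancers, and its hairpin left 66.2% of it. Lineage genes rose all the same. The endoderm genes Cer1 and Sox17 rose by 2.82 ± 0.52 (SE, n = 2) and 2.43 ± 0.37, Foxa2 by 1.86 ± 0.45, and the trophoblast genes Plac1, Rhox6 and Hand1 by 2.38 ± 0.46, 1.99 ± 0.32 and 1.41 ± 0.41. The organiser genes Lhx1 and Gsc rose by 2.29 ± 0.58 and 2.08 ± 0.39. Zscan4c and Usp17la, genes of the cleavage-stage program that rare ES cells enter (2C-like), rose by 1.84 ± 0.39 and 1.83 ± 0.31, Tcstv1 by 1.11 ± 0.33 (adjusted p = 0.0366), and Tcstv3 was at least 5.09-fold higher. The largest changes also took in Neto1 (at least 15.2-fold higher), C1s2 (3.32 ± 0.59, well above background on 2 of 30 controls), Mab21l2 (2.87 ± 0.52, on 8), Prmt8 (at least 5.12-fold lower), Dnajc6 (-1.93 ± 0.21), Pdcl2 (-1.87 ± 0.24) and Tek (-1.80 ± 0.38). A region at 85952719 to 85958369 on chromosome 8 rose by 4.81 ± 0.49 (well above background on 1 of 30 controls).

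The Sox2 knockdown changed 972 features, 462 upward and 510 downward, 350 of them by at least 2-fold. One array moves this count and its balance: without replicate 1 it was 218 (174 upward, 44 downward) and without replicate 2 it was 633 (220 upward, 413 downward). It was 600 with normexp, 203 when fitted with its controls alone, 1831 with the slide as a block and 4986 against clonetechGfp_437 and pLKO alone. Its 2C-like list averaged 1.11, with 4 of 8 genes higher (camera adjusted p = 0.00341 with an estimated correlation). The trophectoderm list averaged 0.68, with 6 higher and 9 when adjusted over the list alone (0.00676 with an estimated correlation, 0.119 with the slide as a block, and 0.385 against the 2 most replicated control hairpins alone). The remaining calls were lost with an estimated correlation: mesoderm 0.84 (adjusted p = 0.102), endoderm 0.53 (0.0905), pluripotency -0.20 (0.413), primed epiblast 0.24 (0.577), feeder markers 0.26 (0.48), interferon 0.39 (0.533) and cell cycle -0.17 (0.359).

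Among the other protein gene knockdowns, those of Setdb1, Ep400, Chd1, Cbx3 and Paf1 raised the 2C-like genes; genes named here are members of the fixed lists. With Setdb1 depleted, Usp17la rose by 6.33 ± 0.31 (SE, n = 2), Zscan4c by 5.42 ± 0.39 and Tcstv1 by 3.80 ± 0.33, Tcstv3 was at least 21.9-fold and Zfp352 at least 12.7-fold higher, and Pou5f1 fell by 0.78 (adjusted p = 0.00427). Knockdown of the chromatin remodeller Ep400 raised Usp17la by 4.29 ± 0.31, Zscan4c by 4.26 ± 0.39 and Tcstv1 by 3.29 ± 0.33. Knockdown of the remodeller Chd1 raised Zscan4c by 3.74 ± 0.39, Tcstv1 by 3.73 ± 0.33 and Usp17la by 3.28 ± 0.31. Smaller rises followed the loss of Cbx3 (Usp17la 2.64 ± 0.31, Zscan4c 2.45) and of the elongation factor Paf1 (Usp17la 2.12 ± 0.31, Zscan4c 1.88). The list as a whole averaged 3.63 for Setdb1 (7 of 8 higher), 2.65 for Chd1 (7) and 2.52 for Ep400 (6), with adjusted p = 2.4e-14, 4.4e-10 and 4.1e-04 under an estimated correlation. For Cbx3 it averaged 1.26 (3 higher, 5 when adjusted over the list alone, p adjusted 0.00259) and for Paf1 1.13 (3 and 5, 0.0149, with adjusted p = 0.0704 when the slide was a block). Without the 2 most replicated control hairpins the calls for Cbx3 (adjusted p = 0.0504) and Paf1 (0.13) were lost. The list was called higher in 9 of 42 protein gene knockdowns and in 6 with an estimated correlation, and lower in 0.

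**Figure D3:**
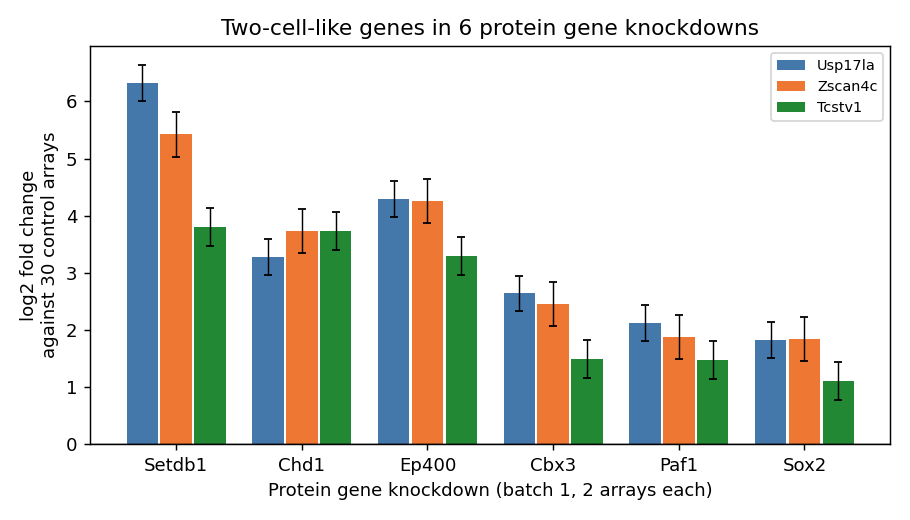
Log2 fold change of 2C-like genes in 6 protein gene knockdowns of batch 1 (2 arrays each) against 30 control arrays, with bars as standard errors. Setdb1 gives the largest values (Usp17la 6.33) and in the Sox2 knockdown Zscan4c reaches 1.84.

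Knockdown of Stat3, which relays the LIF signal, parted naive from primed genes. Tfcp2l1, Esrrb and Klf4, factors of the naive state, fell by log2 fold changes of -2.08 ± 0.19 (SE, n = 2), -1.98 ± 0.15 and -1.79 ± 0.17, and Nr0b1 fell by 1.80 ± 0.18. The primed genes Fgf5, Pim2, Dnmt3b and Otx2 rose by 1.74 ± 0.22, 1.40 ± 0.23, 1.29 ± 0.18 and 1.16 ± 0.23. The pluripotency list averaged -0.90, with 18 lower and 1 higher (adjusted p = 4.9e-07 with an estimated correlation), and the primed list 0.97, with 9 of 12 higher (0.0114, and 0.0697 with the slide as a block). On the 1 array of the Esrrb knockdown Nr0b1 (-2.20), Tfcp2l1 (-1.18) and Klf4 (-0.96) lay below the control mean, and the pluripotency list averaged -0.49, with no spread of its own to test it by. Knockdown of Thap11, a zinc-finger factor of ES cell growth, lowered Klf4 (-0.98 ± 0.17) and Dnmt3l (-0.83 ± 0.17), with a list mean of -0.42 (12 lower, 0.0213, 0.16 with the slide as a block and 0.101 against the 2 most replicated control hairpins alone). The list rose with Mycn (0.28, 7 higher, 0.0271, but 0.0872 against those 2 hairpins alone and 0.0647 without them), where Dppa3 rose by 1.19 ± 0.14, and with Ruvbl1 (0.34, 2 higher and 15 when adjusted over the list alone, 0.00973). Knockdowns of one batch share their controls, so part of any similarity between them can come from these.

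Lineage lists moved in a few protein gene knockdowns. Eed knockdown raised the mesoderm factors Mesp1 and Mixl1 by 3.09 ± 0.58 and 3.09 ± 0.69 (SE, n = 2), Evx1 by 2.42 ± 0.49, T by 2.04 ± 0.50 and the cardiac factor Isl1 by 1.91 ± 0.25, with 14 of 20 list genes higher (mean 1.45, adjusted p = 0.00714 with an estimated correlation). With the feeder mean as a covariate the list averaged 0.78 and the call was lost (adjusted p = 0.204). Knockdown of Klf5 lowered the list (mean -0.94, 7 lower, 0.0272), where Wnt3a fell by 1.77 ± 0.26, T fell by 1.90 ± 0.50 and Lhx1 fell by 2.09 ± 0.58; the call was lost against the 2 most replicated control hairpins alone (adjusted p = 0.932), where T (0.26) and Lhx1 (0.36) turned, with the scan day as a block (0.0516) and with the feeder covariate (0.119). Knockdown of Cnot3, a subunit of the deadenylase complex, raised Hand1 by 2.84 ± 0.41, Plac1 by 1.89 ± 0.46, Cdx2 by 1.61 ± 0.52 and the keratin gene Krt19 by 1.37 ± 0.30, with 9 trophectoderm genes higher (mean 0.82, 0.00377, and 0.12 against those 2 hairpins alone). Ep400 knockdown lowered feeder genes such as Col1a1 (-2.37 ± 0.21), with Mmp3 at least 20.6-fold lower and 24 of 29 markers lower (mean -1.29, adjusted p = 0.0148 with an estimated correlation, and 0.0562 against those 2 hairpins alone).

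Over all 42 protein gene knockdowns, calls at the preset correlation shrank with an estimated correlation. The pluripotency list was called higher in 10 and lower in 18, and in 2 and 5 with an estimated correlation, 1 of them on 1 array. The same counts were 12 and 3 against 3 and 0 for trophectoderm, 12 and 15 against 1 and 2 for primed epiblast, 9 and 10 against 1 and 1 for mesoderm, 8 and 7 against 1 and 0 for p53 targets, 3 and 6 against 0 and 1 for cell cycle, and 14 and 12 against 0 and 1 for feeder markers. No call held for interferon response (14 and 7 at the preset correlation), endoderm (5 and 2), integrated stress response (3 and 2), neuroectoderm (0 and 3) or Polycomb factors (0 and 8).

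The central question was how strongly lincRNA knockdowns change expression beside knockdowns of known regulators. In batch 1 the 104 lincRNA knockdowns with at least 2 arrays changed a median of 280 features by at least 2-fold (quartiles 148 and 436, range 14 to 1820), and the 34 protein gene knockdowns a median of 316.5 (158 and 491, range 20 to 3267). The difference in medians did not pass the permutation test (p = 0.413). The order of the medians turned with the settings: they were 649.5 (lincRNA) and 541.5 (protein gene) without clonetechGfp_437 and pLKO, the 2 most replicated control hairpins, and 531 and 1142 against these alone. Without a fold threshold they were 1035 and 997.5, and with normexp 45 and 57. Drawn pairs of control arrays from different hairpins, tested against the other controls, gave a median of 20 and a 95th percentile of 1224, above which lay 3 lincRNA and 2 protein gene knockdowns. The 100 draws share 30 arrays and mix hairpins within a pair, so no test was based on them. Control hairpins with several arrays of their own, tested the same way, gave 1142 (clonetechGfp_437), 842 (pLKO), 82 (rfp_402) and 38 (promegaLuc_160), and pairs of arrays of one hairpin gave medians of 830.5 (6 pairs), 705 (10 pairs), 82 (1 pair) and 38 (1 pair). The first 2 of these control hairpins thus lay above the median of either class.

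**Figure D4:**
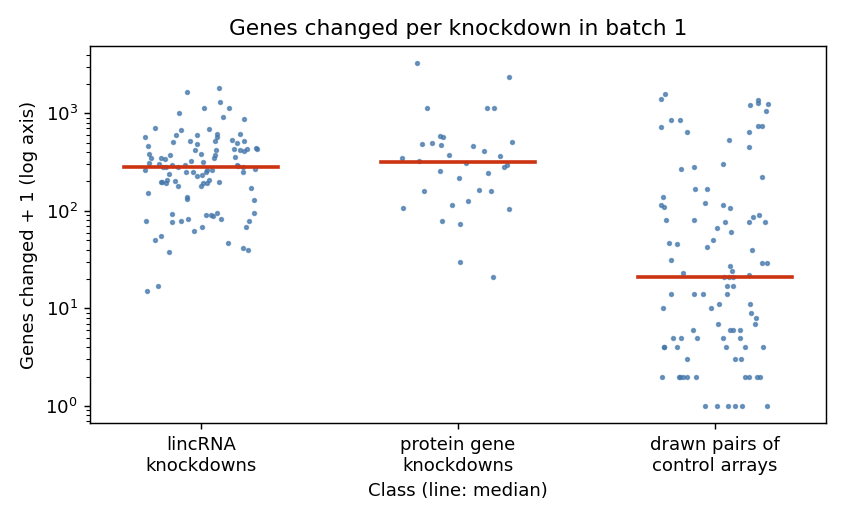
Features changed by at least 2-fold (plus 1, log axis) per knockdown of batch 1 with at least 2 arrays, by class, beside drawn pairs of control arrays, with lines as medians. The medians are 280 for lincRNA knockdowns, 316.5 for protein gene knockdowns and 20 for control pairs.

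Named here are genes moved most by the 5 lincRNA knockdowns with the most changed features, whose overlap was not tested. The choice depends on the model: with the slide as a block linc1610 changed 941 features, fewer than linc1390 (978) and linc1563 (943). The count of linc1623 (1132) lay under that of the control hairpin clonetechGfp_437 (1142). Knockdown of linc1559 (1820 features) raised the chemokine gene Ccl21a by 3.46 ± 0.52 (SE, n = 2; well above background on 2 of 30 controls) and the troponin gene Tnni2 by 3.38 ± 0.34, and left Cer1 at least 26.9-fold and Alox15 at least 18.8-fold lower. Knockdown of linc1610 (1666) raised Mchr1 by 4.81 ± 1.01 and Synpo by 4.08 ± 1.05 and lowered Nipal1 (-2.98 ± 0.39, well above background on 1 of 2 arrays). With the linc1626 hairpin in batch 2 (1312), Uts2b rose by 2.33 ± 0.47 and Lcp2 by 2.26 ± 0.64, Pex14 fell by 3.82 ± 0.46, and Cer1 was at least 9.99-fold lower. Knockdown of linc1555 (1289) left Lrrc72 at least 37.2-fold and Ccr1 at least 31.8-fold higher, and Hydin rose by 5.45 ± 0.58 while Cbr2 fell by 3.42 ± 0.36 (n = 2, well above background on 1). Knockdown of linc1623 (1132) raised the mesendoderm factor Mixl1 by 3.36 ± 0.69, left Cd200r1 at least 9.55-fold higher and A2m at least 9.96-fold lower. None of these lincRNAs was matched to a probe of its own.

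Pluripotency genes fell in a minority of lincRNA knockdowns. The largest list effect followed linc1626 in batch 2, where Nr0b1 fell by 2.21 ± 0.19 (SE, n = 2) along with Pou5f1 (-2.03 ± 0.22), the AKT cofactor gene Tcl1 (-1.86 ± 0.22) and Esrrb (-1.79 ± 0.16), with 19 of 27 list genes lower (mean -0.96, adjusted p = 2.4e-05 with an estimated correlation). With the linc1252 hairpin in batch 2 the nuclear receptor gene Nr5a2 fell by 2.41 ± 0.34 and Lefty2 fell by 1.40 ± 0.20 (list mean -0.65, 12 lower, 1.0e-04). Knockdown of linc1505 in batch 2 lowered Tdgf1 (-1.37 ± 0.30), Pou5f1 (-1.18 ± 0.22) and Sox2 (-0.90 ± 0.15), with a list mean of -0.58 (18 lower, 0.00271). Knockdown of linc1338 in batch 2 lowered Pou5f1 (-1.25 ± 0.22) and Sox2 (-0.88 ± 0.15), with a list mean of -0.51 (13 lower, 0.00377). In batch 1, Tbx3 fell with linc1613 (-1.18), linc1244 (-1.13) and linc1612 (-0.97, SE 0.17 each), and Klf4 fell with linc1612 (-0.85). The list was called lower in 58 of 151 lincRNA knockdowns and higher in 24, and lower in 12 and higher in 3 with an estimated correlation. Of those 12 calls, 3 of them on 1 array, 8 held against the 2 most replicated control hairpins alone, 9 without them, 9 with the slide as a block and all with the feeder mean as a covariate, although the feeder markers rose with linc1626 (0.52), linc1505 (0.42) and linc1338 (0.47). The largest rise was that of linc1300 in batch 2 (mean 0.60, 16 higher and 22 when adjusted over the list alone, 0.00156), where Tcl1 rose by 1.43 ± 0.22 and Dppa3 by 0.86 ± 0.14; the feeder markers averaged -0.54 there, and the call held with the feeder covariate (adjusted p = 0.0104).

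Pou5f1 itself was lower in 20 of 151 lincRNA knockdowns and higher in 0, adjusted over the knockdowns by limma. These were 4 of 119 in batch 1 and 16 of 32 in batch 2, and 2 of the 20 had 1 array. The knockdowns of a batch share its controls, 11 arrays in batch 2, so one error in the control mean moves all of them and the shares were not tested against each other. The median log2 fold change of Pou5f1 over lincRNA knockdowns was -0.01 in batch 1 and -0.65 in batch 2. Its mean level in controls was 5.58 ± 0.24 (SD, n = 30) in batch 1 and 4.86 ± 0.43 (SD, n = 11) in batch 2. Falls of at least 1 log2 unit were seen in 1 knockdown of batch 1 and 6 of batch 2. Pou5f1 was lower in 5 of 42 protein gene knockdowns: its own in both batches, and those of Setdb1, Eed and, on 1 array, Ezh2.

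**Figure D5:**
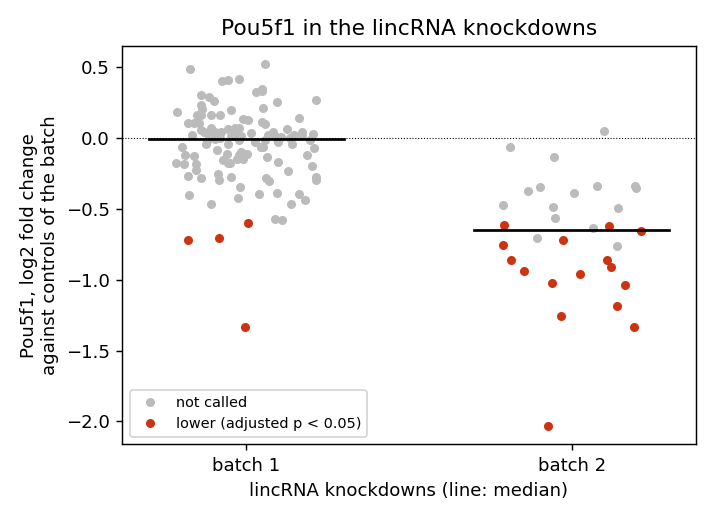
Log2 fold change of Pou5f1 in each lincRNA knockdown against controls of its batch, by batch, with red points lower at adjusted p under 0.05 and lines as medians. The medians are -0.01 in batch 1 and -0.65 in batch 2.

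Mesoderm genes rose in 11 lincRNA knockdowns by the test with an estimated correlation. With the linc1623 hairpin T rose by 2.33 ± 0.50 (SE, n = 2), Evx1 by 2.60 ± 0.49 and Lhx1 by 2.43 ± 0.58 (list mean 1.49, 14 of 20 higher, adjusted p = 0.00676). With the linc1456 hairpin Mixl1 rose by 2.80 ± 0.69, Mesp1 by 2.67 ± 0.58 and T by 1.90 ± 0.50 (mean 1.36, 12 higher and 17 when adjusted over the list alone, 0.00161). Knockdown of linc1390 raised Mesp1 by 3.12 ± 0.58 and Lhx1 by 2.73 ± 0.58 (mean 1.19, 0.0272). On its 1 array linc1471 had Mixl1 higher by 3.86 and Evx1 by 3.26 (mean 1.71), along with the feeder markers (mean 1.08). With the feeder mean as a covariate its mesoderm mean was 0.61, the call of linc1390 (mean 0.72, adjusted p = 0.222) was lost, and those of linc1623 (0.0259) and linc1456 (0.00339) held. Over all 151 knockdowns the list was called higher in 37 and lower in 45 at the preset correlation, and in 11 and 0 with an estimated correlation. Of these 11 calls, 1 of them on 1 array, 7 held with the feeder covariate, and 4 when the 2 most replicated control hairpins were left out.

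Other lists moved in single lincRNA knockdowns. On the 1 array of linc1385 the interferon genes Ifit3, Ifit1 and Usp18 lay above the control mean by 3.06, 2.51 and 2.48 (list mean 1.51). Ifit3 fell by 2.70 ± 0.49 with linc1627 in batch 2 (SE, n = 2; list mean -1.36, 13 of 18 lower, adjusted p = 0.00128 with an estimated correlation). The feeder markers fell there as well (mean -0.73, adjusted p = 0.0274), and with the feeder covariate the interferon mean was -1.05 (0.0165). Trophoblast keratins went opposite ways. Krt19 and Krt7 rose with linc1349 by 1.48 ± 0.22 and 1.44 ± 0.23 (SE, n = 4, list mean 0.50, 9 higher, 0.0235, and 0.197 against the 2 most replicated control hairpins alone). With the linc1557 hairpin Krt19 (-2.22 ± 0.30), Krt18 (-1.88 ± 0.22) and Krt8 (-1.81 ± 0.20) fell, with a list mean of -0.65 (7 lower, 0.0111). With linc1267 in batch 1 the feeder gene Col5a2 fell by 2.40 ± 0.25 and Col1a2 fell by 2.24 ± 0.23 (mean -1.46, 25 of 29 lower, 2.4e-05). The stress genes Chac1, Atf3 and Atf4 rose with linc1421 by 1.11 ± 0.28, 0.89 ± 0.23 and 0.54 ± 0.12 (list mean 0.40, 5 higher, 0.00603). Pax6 rose with linc1230 by 1.28 ± 0.22 and Sox1 by 1.07 ± 0.33 (neuroectoderm mean 0.44, 5 higher, 0.0261, and 0.12 without the 2 most replicated control hairpins), and Zscan4c rose with linc1607 in batch 2 by 1.94 ± 0.41 (2C-like mean 0.98, 4 higher, 0.0197, and 0.0514 with the slide as a block).

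The remaining lists give counts over the 151 lincRNA knockdowns, higher and lower, at the preset and at an estimated correlation. Cell cycle genes were called in 29 and 16 against 9 and 0, all 9 in batch 2 with lower feeder markers (-1.30 to -0.40) and none of them held with the feeder covariate (3 of the 9 had 1 array), feeder markers in 31 and 71 against 1 and 5, and interferon genes in 42 and 27 against 1 and 3. Trophectoderm was called in 25 and 15 against 4 and 1, p53 targets in 22 and 24 against 2 and 1, integrated stress response in 15 and 18 against 2 and 0, neuroectoderm in 9 and 1 against 1 and 0, and the 2C-like list in 5 and 4 against 1 and 0. No call held for primed epiblast (29 and 22 at the preset correlation), endoderm (19 and 8) or Polycomb factors (18 and 7). Of all 57 lincRNA knockdown calls at an estimated correlation, 10 of them on 1 array, 36 held with the slide as a block and 55 with the scan day as a block. Of the 51 outside the feeder list, 34 held with the feeder covariate.

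The class averages ask whether lincRNA hairpins share a response that control hairpins lack. On average the RNA-binding cold-shock gene Cirbp fell by 1.09 ± 0.11 on the log2 scale (SE, 151 lincRNA against 32 control hairpins), and the nicotinic receptor gene Chrna7 fell by 0.94 ± 0.10. The matrix-attachment factor Banp rose by 0.89 ± 0.09, the Pur-family gene Purg by 0.80 ± 0.06 and the splicing-related gene Rsrp1 by 0.73 ± 0.08. With the fitted batch term removed, Cirbp, Banp and Purg lay on the same side of the pooled control mean in 151 of 151 lincRNA hairpins. This count does not set each hairpin against the controls of its own batch. The fit gives 1 average over both batches, which need not hold in each, and a difference between the batches was not tested. Other large average changes were those of Rsph4a (-1.47 ± 0.15, well above background on 22 of 41 control and 35 of 284 lincRNA arrays), Il20rb (-1.12 ± 0.12), Cxcr6 (-1.01 ± 0.23), Cntd1 (1.05 ± 0.19) and Fhad1 (0.87 ± 0.18). Against the 2 most replicated control hairpins as the batch 1 controls Cntd1 (-0.21), Fhad1 (-0.30) and Cxcr6 (0.0097) turned and did not pass. Cirbp (-0.27), Chrna7 (-0.21), Banp (0.16), Purg (0.26), Rsrp1 (0.33), Rsph4a (-0.48) and Il20rb (-0.35) shrank and no longer passed. This fit kept the 11 control hairpins of batch 2 and a single batch term, so its values weigh batch 2 most. They do not set lincRNA hairpins against the 2 hairpins alone. Within batch 1 Cntd1 had a mean level of -3.25 in lincRNA hairpins, -1.90 in the 2 hairpins and -5.05 in the other 19 controls. The batch 1 lincRNA level lay below that of the 2 hairpins for Purg (1.52 against 1.69) and Banp (3.55 against 3.62). Among list members, Nr0b1 (-0.47 ± 0.10), Pou5f1 (-0.27 ± 0.09), Klf4 (-0.27 ± 0.07) and the feeder gene Prrx1 (-0.51 ± 0.09) fell. With the same 2 hairpins as the batch 1 controls Pou5f1 alone of these 4 still passed limma's test (-0.62, adjusted p = 0.00817). Nr0b1 (-0.38), Klf4 (-0.15) and Prrx1 (-0.17) did not. The median change of Pou5f1 over lincRNA knockdowns was -0.01 in batch 1 and -0.65 in batch 2. The value of -0.62 therefore reflects mainly batch 2 and its shared controls, not the 2 hairpins. In all 7402 features changed, 3376 upward and 4026 downward, but only 14 by at least 2-fold, and the median size of a change was 0.232. Of intergenic regions 409 rose and 835 fell.

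The lincRNA class result depended on the form of the model and on which control hairpins were used. With single arrays and the hairpin as a random block 4913 features changed. With the slide added as a block 2855 of these (58.1%) stayed called, all 4913 kept their sign, and their median difference went from 0.228 to 0.191 (median SE 0.0604 and 0.0606). With the 2 most replicated control hairpins as the only batch 1 controls, 223 features changed. Draws of 2 other batch 1 control hairpins gave a median of 755.5, so much of this drop goes with having fewer controls. Within scan days, which hold 2 to 11 control arrays each, limma called 34, 0, 5, 0, 0 and 104 features on days 2 to 7. At an unadjusted p under 0.05 it called 643, 1609, 1830, 2905, 1092 and 3460. Of the lists, the feeder markers averaged -0.22, with 14 lower and 17 when adjusted over the list alone (camera adjusted p = 6.1e-05), and cell cycle genes 0.07, with 5 higher (0.0336); with an estimated correlation adjusted p = 0.963 for both. The pluripotency list averaged -0.09 with 5 lower (adjusted p = 0.114) and the other lists were not called.

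The protein gene class averages weigh 42 hairpins alike, the Pou5f1 hairpins among them, so a raised mean need not be a change common to them. Krt7 rose on average by 0.72 ± 0.16 (SE, 42 against 32 hairpins, adjusted p = 0.00177), Hand1 by 0.70 ± 0.20, Rhox6 by 0.69 ± 0.20 and Rhox9 by 0.58 ± 0.19. Nr0b1 fell by 0.54 ± 0.12 and Pou5f1 fell by 0.40 ± 0.11. Fhad1 (0.73), Slc2a12 (0.72), Cntd1 (0.72) and Gpat3 (0.58 ± 0.11) were among the largest rises, and Rsph4a (-1.04 ± 0.19), Cabs1 (-0.72), Chrna7 (-0.63 ± 0.13) and Map7d3 (-0.58 ± 0.10) among the largest falls. With the fitted batch term removed, Krt7 lay above the pooled control mean in 33 and Hand1 in 30 of the 42 hairpins. Here 1682 features changed, 694 upward and 988 downward, and 1 by at least 2-fold. Against the 2 most replicated control hairpins as the batch 1 controls 905 changed, and of the genes named above only Gpat3 (0.60, adjusted p = 0.032) and Pou5f1 (-0.76, 0.00146) still passed. Fhad1 (-0.49), Cntd1 (-0.61) and Chrna7 (0.14) turned, and Rsph4a went to -0.0019. Krt7 (0.36), Hand1 (0.79, adjusted p = 0.126), Rhox6 (0.91, 0.0642) and Rhox9 (0.68, 0.192) did not pass limma's test. Pou5f1 was itself a target, and its own depletion (-3.10 in batch 1, -4.09 in batch 2) enters its class mean in every fit. With fewer batch 1 controls the 2 protein gene hairpins of batch 2, that of Pou5f1 among them, also carry more weight. Within scan days limma called 30, 0, 0, 0, 0 and 6056 features on days 2 to 7, and 608, 1481, 818, 1614, 751 and 10080 at an unadjusted p under 0.05. The protein gene arrays of day 7 are the 4 of batch 2. Day 1 was not fitted this way, and with its arrays left out of the class fit 931 features changed. The trophectoderm list averaged 0.26, with 5 higher and 11 when adjusted over the list alone (camera adjusted p = 4.3e-07, lost with an estimated correlation, 0.107). The pluripotency (-0.16, 5 lower, 9.6e-05), primed epiblast (-0.22, 3 lower, 0.00395), 2C-like (0.25, 1 higher, 0.00601) and p53 lists (0.07, 1 higher, 0.00277) were also called. At an estimated correlation camera gave each of them adjusted p = 0.347. Mesoderm was called as well (-0.26, with 1 gene higher and 0 lower, 0.04, and 0.636 at an estimated correlation). The pluripotency list holds targets of these hairpins, among them Pou5f1, Esrrb and Klf4, whose own depletion enters its mean.

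The direct test between the classes found 3505 features, 2064 higher and 1441 lower in lincRNA hairpins and 0 by at least 2-fold. Rsrp1 was higher with lincRNA hairpins by 0.67 ± 0.07 (SE, 151 against 42 hairpins), Spon1 by 0.66 ± 0.14, the carbonic anhydrase gene Car14 by 0.63 ± 0.12 and Pim2 by 0.48 ± 0.11. The 2C-like genes Usp17la (-0.71 ± 0.14) and Zscan4c (-0.64 ± 0.16), the receptor gene Il20rb (-0.82 ± 0.11), Cirbp (-0.57 ± 0.10) and the cytokine gene Il6 (-0.55 ± 0.13) were lower. The lists called were feeder markers (-0.16, 6 lower, adjusted p = 2.9e-07), cell cycle (0.09, 7 higher, 9.4e-06), 2C-like (-0.34, 3 lower, 2.3e-04), trophectoderm (-0.18, 4 lower, 2.9e-04), Polycomb factors (0.07, 5 higher, 0.00101) and p53 targets (-0.06, 2 lower, 0.0183). None held with an estimated correlation, where adjusted p ranged from 0.234 to 0.338. The Polycomb list holds targets of protein gene hairpins, among them Eed, Setdb1 and Cbx3. These were not left out, so their own depletion enters the Polycomb difference.

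If a hairpin acts through its target, another hairpin against the same target should give a similar profile. The 7 pairs of batch 1 hairpins against one lincRNA had a mean r of 0.206 across genes, from 0.501 for linc1253 to -0.0838 for linc1490. Pairs of different lincRNAs averaged 0.148 (exact permutation p = 0.0972). For targets profiled in both batches the 8 pairs had a mean r of 0.165 against 0.00427 for other pairings (exact permutation p = 0.0108), led by Pou5f1 with 0.542, and XM_132755 gave 0.203. Without Pou5f1 the mean was 0.111 (exact permutation p = 0.0778), and for the 3 lincRNA hairpins with one name 0.0968 (0.167), so the call does not hold without Pou5f1. Genes are not independent replicates in these correlations. Likeness to the Pou5f1 knockdown was judged by the highest of 21 control hairpins (0.161). Above it lay 1 of 119 lincRNA hairpins, linc1471 (r = 0.275, on 1 array), and 4 of 39 protein gene hairpins (highest 0.21). If lincRNA hairpins scored like control hairpins, 5.4 of them would lie above it by chance. Their median r was -0.0978 against 0.0389 for control hairpins, so that count cannot serve as a reference. No chance count was taken for the protein gene hairpins.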

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

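The tests with the slide as a block, with the feeder covariate and with the most replicated control hairpins for the lincRNA class, and the test of Pou5f1 depletion, were chosen only after the results were seen; the splits of the samples and the test of dilution by feeder RNA were set before. Lists are given here where the Pou5f1 or XM_132755 knockdown moved them by different amounts in batches 1 and 2, by a camera test of the difference itself with an estimated correlation.

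In the Pou5f1 knockdown the trophectoderm list was higher in batch 1 than in batch 2 by 2.24 on the log2 scale (adjusted p = 6.3e-08). Cdx2 alone differed by 6.86 ± 0.69, having risen in batch 1 and fallen in batch 2. The cell cycle list differed by 1.02 (adjusted p = 6.3e-08), the pluripotency list by 0.83 (6.7e-04) and the Polycomb and chromatin factor list by 0.42 (0.0186), each lower in batch 2. The p53 target list differed by -0.50 (0.0262), higher in batch 2. In the XM_132755 knockdown the pluripotency list was lower in batch 2, with a difference of 0.36 (0.0197). The labels of these knockdowns differ between the batches and do not show whether the hairpin was the same. A difference between hairpins therefore stays open beside one between batches.

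A weaker depletion of Pou5f1 in batch 2 would explain the smaller trophectoderm response, but Pou5f1 was lower in batch 2 by 0.99 (SE 0.28). Dilution of all raised genes by more feeder RNA in batch 2 was expected to lower the trophectoderm genes no more than others with a like rise. The 16 trophectoderm genes raised in batch 1 fell short in batch 2 by a median of 2.34, against a median of 2.01 and an upper 95% bound of 2.24 for 10000 sets of other genes with a like rise. The first test argues against weaker depletion as the cause. The second matched genes on their batch 1 rise alone and not on their level in controls. Elf5, Hand1 and Plac1 were at background on many batch 1 controls, so it cannot tell dilution near background from a specific shortfall. A different stage of the response at day 4, a difference between hairpins and a difference in culture between batches were not tested.

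The lincRNA class difference is wide and shallow, with 7402 features called and few at 2-fold. In 100 splits of the hairpins within batches, the real one among them, the highest other count was 118. It was 1260 for the protein gene class (1682 in the data) and 4 for the test between the classes (3505). For the Pou5f1 knockdown in batch 1 (9595), splits of its 3 arrays and the 30 control arrays reached 5368. In each comparison only the real split gave as many features, so a random grouping would seldom do so. The splits keep neither slide nor scan day. They therefore cannot exclude culture or plate conditions spread unevenly over the classes. With the feeder mean as a covariate 4867 features (65.8%) stayed called in the same direction, which argues against feeder content as the whole cause. Of 4913 features called with the hairpin as a random block, 2855 (58.1%) stayed called with the slide added, and their median difference went from 0.228 to 0.191 at a median SE of 0.0604 and 0.0606. That fit kept 3024 (40.9%) of the 7402 features called on hairpin means, but it differs from theirs in form as well as in the slide. The retained differences argue against slide differences as the whole cause and leave a part open.

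Control hairpins differ among themselves along the same genes. Cirbp had a mean log2 level of 3.31 in the 2 most replicated batch 1 control hairpins, clonetechGfp_437 and pLKO, against 4.56 ± 0.21 (SD) in the other 19 and 2.95 ± 0.55 in lincRNA hairpins. Purg stood at 1.69, 0.39 ± 0.26 and 1.52 ± 0.26 and Banp at 3.62, 2.21 ± 0.25 and 3.55 ± 0.48. With these 2 hairpins as the batch 1 controls 223 features changed, fewer than in each of 100 draws of 2 of the other hairpins (lowest 424, median 755.5). The draws were far below 7402 too, so much of the drop goes with having fewer batch 1 controls. The 2 hairpins are means of 4 and 5 arrays and the drawn ones of at most 2 each. Noisier control means could add calls to the draws, so the comparison is not like for like. The levels above leave a candidate explanation for part of the class difference. It is a culture or plate condition that most control hairpins had and the lincRNA hairpins and these 2 did not. A response to any knockdown was not tested apart from it.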

How the results depend on the processing

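The alternatives with scan-day blocks or single scan days, slide and scan-day blocks with a random hairpin, controls with or without clonetechGfp_437 and pLKO, the feeder covariate for list calls, and fewer pairs in the comparison of batches were chosen after seeing the data. Of the values of named genes under all alternatives, 6308 kept direction and side of the threshold, 407 kept direction but no longer passed, 1 came to pass and 19 reversed. Of the main results 112 stayed close, 40 moved and 2 no longer passed. The band counted as close was wide. It took in 2470 features for the protein gene class (1682 as reported) and 8900 for the lincRNA class (7402) with batch 1 hairpins alone. Quantile normalisation, the filter on at least 50% of arrays, the mean of a gene's probes, batch 1 hairpins alone, Spearman correlation and the 2000 most variable genes moved none of the main results out of that band. Among named genes normexp weakened 57 of 375, the feeder covariate 36 of 366 and the slide as a block 31 of 307. The controls clonetechGfp_437 and pLKO alone weakened 40 of 355 and reversed 13, knockdown and control arrays alone weakened 33 of 91, and scan day 1 alone 23 of 58. The cause was not tested except where the setting itself removes samples or thresholds.

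Without a fold threshold the median counts per knockdown were 1035 for lincRNA and 997.5 for protein genes, and with an estimated correlation 12 lincRNA knockdowns had the pluripotency list lower. Normexp gave 600 features for Sox2, medians of 45 and 57 and 776 features for the protein gene class; it moved the median of all genes to 0.37 for Pou5f1 in batch 2 (0.117 as reported) and to -0.107 for Sox2. Without a filter the protein gene median was 479.5.

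Without pLKO the XM_132755 knockdown in batch 1 gave 105 features. Without clonetechGfp_437 and pLKO it gave 79, the medians were 649.5 (lincRNA) and 541.5 (protein genes), the protein gene class gave 2782, and Eomes in the Pou5f1 knockdown of batch 1 went to -0.022. With these 2 hairpins alone XM_132755 gave 5255 features, Sox2 4986, the medians were 531 and 1142, and the classes gave 223 (lincRNA) and 905 (protein gene). Reversed with them were Nr0b1 (0.27) and Zfp42 (0.043) in the XM_132755 knockdown and T (0.26) and Lhx1 (0.36) with Klf5, none of them still called. In the lincRNA class Cntd1 (-0.21), Fhad1 (-0.30), A2m (-0.041), Pgbd5 (-0.071) and Cxcr6 (0.0097) reversed, and in the protein gene class Fhad1 (-0.49), Cntd1 (-0.61), Chrna7 (0.14) and Plppr4 (0.27). The class fits kept the controls of batch 2, so dropping most batch 1 controls gave batch 2 more weight in them.

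With the feeder covariate XM_132755 gave 102 features, the test between the classes 2002, and 3 lincRNA knockdowns resembled that of Pou5f1. Eomes (-0.82, past the threshold in the new direction, adjusted p = 0.00433) and, not past it, Cdkn1a (-0.35) in the Pou5f1 knockdown of batch 1, Elf5 (-0.29) in that of batch 2, at background, and T (-0.24) with linc1471 reversed. The slide as a block gave 1831 features for Sox2, and the scan day as a block 51 for XM_132755. Numbers 1 and 2 did not pair the samples: over 138 groups and 9453 pairs the deviations of samples with one number had a mean r of 0.0116 (33.9% above 0.1). With the replicate block, in batch 1, Pou5f1 gave 9730 features, XM_132755 143 and Sox2 885, and Pou5f1 was lower in 4 lincRNA knockdowns, since batch 2 is left out.

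With the hairpin as a random block the lincRNA, protein gene and between-class tests gave 4913, 931 and 5592 features, with scan day added 3466 (lincRNA) and 861 (protein gene), and with slide added 3127 (lincRNA) and 5415 (between classes). Without scan day 1 the protein gene class also gave 931. Leaving out each array, XM_132755 in batch 1 gave 37 to 40 features and Sox2 218 to 633, the lone array assumed to vary like other groups; fitted with their controls alone they gave 15 and 203. On scan day 1 alone XM_132755 gave 0 by limma (1999 at an unadjusted p under 0.05), and Eomes with Pou5f1 was -0.22. The correlation between batches was 0.111 without Pou5f1 (exact permutation p = 0.0778) and 0.0968 for the 3 hairpins with one name (0.167).

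Signal over background, 43.2% to 69.3% of spots in controls of batch 1, limits dim genes to bounds. Lower Nanog, neighbouring genes and their narrower window were not run.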

Other observations

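The tests on protein complexes and on signal quality were chosen only after their profiles were seen, and the tests of shared slides and feeder content for Tip60-p400 were set before their results. Several gene programs moved in single knockdowns beyond those already described. Interferon genes fell with linc1602 in batch 1, Ifit3 by a log2 fold change of -2.23 ± 0.47 (SE, n = 2), with Ifi44 at least 6.61-fold lower (list mean -1.05, adjusted p = 0.0184 with an estimated correlation, 0.0652 with the slide as a block and 0.0609 without the 2 most replicated control hairpins). They fell also with linc1405 in batch 2 (mean -0.99, 11 of 18 lower, 0.0328, and 0.0672 with the slide as a block). The feeder markers fell there too (mean -0.80, adjusted p = 0.017), and with the feeder covariate the interferon mean was -0.65 (0.204). The placental homeobox genes Rhox9 and Rhox6 rose with linc1614 by 1.91 ± 0.30 and 1.84 ± 0.32 (trophectoderm mean 0.49, 3 higher, 0.0366, but 0.285 with the slide and 0.0751 with the scan day as a block, 0.0614 with the feeder covariate and 0.343 against the 2 most replicated control hairpins alone). The p53 target list rose with linc1338 in batch 2 (mean 0.33, 8 higher, 0.0368, and 0.112 with the slide as a block, 0.0805 with the feeder covariate), where Mdm2 rose by 0.63 ± 0.15, and fell with linc1230 (mean -0.28, 4 lower, 0.0343, but 0.0551 with the slide and 0.052 with the scan day as a block, and 0.0915 without the 2 most replicated control hairpins), where Zmat3 fell by 0.83 ± 0.11. Cyclin genes rose in batch 2 with linc1621, Ccnb2 by 0.86 ± 0.15 and Ccna2 by 0.83 ± 0.11 (cell cycle mean 0.42, 8 higher, 0.0314, and 0.107 with the slide as a block); the feeder markers averaged -0.67 there, and the call was lost with the feeder covariate (0.154).

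Profiles of some protein gene knockdowns resembled each other across genes. The closest pairs, each set against a different part of the controls, were Ring1 and Tcl1 (r = 0.62), Ring1 and Zfp42 (0.595), and Tcl1 and Zfp42 each with Jarid2 (0.582). These arrays had many spots well above background (58.1%, 59.9%, 58.7% and 65.0% for Ring1, Tcl1, Zfp42 and Jarid2), and with this share as a covariate the values were 0.586, 0.57, 0.459 and 0.492. The genes of a profile are not independent, and no test was run on single pairs.

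Subunits of one complex might give like profiles. For the 4 subunits of the Tip60-p400 acetyltransferase complex the mean r was 0.286 (0.0747 to 0.392), above the upper 95% of drawn sets of 4 protein gene knockdowns (0.202, permutation p = 0.0139, adjusted over both complexes 0.0279). The 8 arrays lay on 8 slides, so no pair of them shared a slide, and the mean r with a slide block (0.303) adds nothing to that. With the share of spots well above background as a covariate the mean r was 0.292 (permutation p = 0.0188, upper 95% of drawn sets 0.222), which argues against signal quality as the whole cause. With the feeder mean as a covariate it was 0.152 (permutation p = 0.133), so a shared effect on feeder content stays open. For the 4 subunits of Polycomb repressive complex 2 the mean r was 0.0454 (-0.273 to 0.39, permutation p = 0.423), which decides nothing either way.

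Among 81810 pairs of arrays none held identical values, and the highest correlation was 0.993. The median within a knockdown was 0.984. Of groups with 4 to 10 arrays, 2 were tested in 12 tests for an array far from the others, and none was found.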
